A study of Mus musculus with 8 samples.

How the data were processed

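RNA from 4 Fli-1 knockout (KO) and 4 wild-type (WT) samples of sorted mouse LSK cells was extracted with the PicoPure kit after 6 days of co-culture, and libraries of polyadenylated RNA were made with a TruSeq kit, per the labels' protocols. The labels name 2 TruSeq kits, of which 1 keeps strand and the other does not, without saying which library was made with which, so a kit difference between libraries could not be examined. The values are whole-number read counts per gene, as the authors deposited them in a single table of 8 columns. Per the submitters' processing notes the tools were FastQC 0.11.8, Trim Galore 0.6.4, STAR 2.6.1d, Subread 1.6.4 and featureCounts, and the builds mm10 and GRCm38, which name the same mouse assembly. The table also holds the 5 special rows that HTSeq-count writes. Which counter made it, which annotation it used and whether it used strand are not given in the sources used here.

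Those 5 rows name no gene and were left out of library sizes and tests. Reads in no gene took 10.5% to 12.1% of all counted reads per library. Ambiguous reads took 0.737% to 0.759% in KO and 0.764% to 0.782% in WT, without overlap. Reads aligned to more than 1 place took 24.8% to 25.3% in KO and 25.7% to 26.3% in WT, also without overlap. Genes with near-identical copies, such as the Mcpt and Tps protease genes and the Bcl2a1 genes, may therefore have lost reads, and their levels are uncertain. Genes with less similar relatives, such as the H2 class II genes, may have lost reads too. Of the 153 genes examined by name, exons of 13 overlap another gene on the same strand and those of 45 a gene on the other strand in GENCODE vM21 (GRCm38). For these, reads of the partner may be included. All 153 symbols were located in that annotation, and coordinates are 1-based. The ribosomal RNA precursor Rn45s took 0.654% to 0.844% of gene counts in KO and 0.766% to 1.35% in WT. A column was given to a sample only where its name matched that sample's labels.

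Of 24420 gene rows, 6395 had no count in any library, and 13020 passed edgeR's filterByExpr with the genotype as group. Counts were scaled with TMM factors and tested with edgeR 4.0.16 (estimateDisp, robust glmQLFit and glmQLFTest) in R 4.3.3, with genotype as the sole term. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called changed at an adjusted p under 0.05. The common biological coefficient of variation was 10.2%. CPM values are TMM-normalised, and standard errors of log2 fold changes were derived from the quasi-likelihood F statistic. A level of 1 CPM rests on about 20 reads per library. Wide errors occur both for genes with few WT reads, such as Dnase1l3 (SE 0.612), and for genes with many reads whose libraries differed, such as F13a1 (SE 0.703) and Elane (SE 1.23).

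Gene lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with adjustment over the 24 lists that had at least 5 tested members. The 25 lists, the design, the rule for named genes and most alternatives were fixed before the data were examined. They covered the heptad, other ETS factors, stem cell identity, G1/S, G2/M, quiescence, granulocyte-monocyte, erythroid, megakaryocyte, lymphoid, mast cell, macrophage and dendritic cell, endothelial, stromal, adhesion, cytokine, Notch, interferon, p53, BCL2, MYC and ribosome biogenesis, NF-kB, glycolysis, cholesterol and mitochondrial genes. With an estimated correlation, none of the 8 list calls held in camera, 1 of 24 lists having an unadjusted p under 0.05, while fry (limma) called 14. Another 4 lists (further mast cell markers, further dendritic cell markers, hypoxia response outside glycolysis, ATF4 and amino acid response) were written after the genes with the largest changes had been seen and before the values of their own members were.

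The rule for named genes took Fli1, the heptad and ETS members, the 10 largest rises and the 10 largest falls among changed genes with a mean of at least 5 CPM and no overlap between groups, leaving out symbols of unnamed gene models, and the 4 members of each list with the lowest p. Named outside that rule, after their values were seen, were Myc, Ldhb, Ccnd3, Lyz2, Cd68, Pcsk9, Ccl9, Kit, Cd34, Cpa3, Dntt, Cd74, Slc18a2, the examples from the 4 later lists and the members of the chromosome 14 protease cluster.

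Pairs of libraries within a group differed by more than sampling noise, with a chi-square per degree of freedom between 2.61 and 29.1 over genes with at least 20 summed counts, so that no library was a copy of another. Replicate numbers 1 to 4 occur in both groups. Deviations from the group means of KO and WT libraries with the same number correlated at 0.286 to 0.474 across genes in all 4 pairs, which met the rule for pairing (every pair over 0.1). Libraries with different numbers correlated at -0.419 to 0.323, the highest being KO replicate 4 with WT replicate 3 (0.323) and KO replicate 3 with WT replicate 4 (0.300), and 5 of the 8 libraries correlated best with their own number. The second principal component (10.2% of variance) set numbers 1 and 2 apart from 3 and 4. This pairing comes from the data, not from the labels. A fit with the replicate number as a block was therefore compared, and its values stand beside the calls it changed and the counts of calls it moved by over 1.5 times.

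Alternatives were median-of-ratios factors, library size only, no low-count filter, a stricter filter (at least 1 CPM in 4 libraries and a mean count of at least 50), the DESeq2 1.42.0 Wald test, limma-voom with quality weights, the replicate block, each library left out, camera with an estimated correlation, fry, and lists without shared genes. Leaving out Rn45s, combining the estimated correlation with the block, and the alternatives for the 4 later lists were added after the data were seen. The edgeR and camera steps were tested on simulated counts for 12891 genes with 50 genes changed at each of 4 sizes for the comparison of KO with WT. They recovered 46% of genes changed 1.25-fold, 74% at 1.5-fold, 78% at 2-fold and 90% at 4-fold with 12 false calls, and called none of the 24 unchanged lists. Simulated genes were drawn independently, whereas the estimated inter-gene correlation in the data reached 0.858 (G2/M list). Far fewer genes changed in the simulation than the 67.4% called in the data. The simulation therefore cannot vouch for camera with correlated genes or for the rate of false calls in these data.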

Results

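Gene expression was measured by RNA sequencing in mouse LSK cells, the lineage-negative fraction that carries Sca-1 and c-Kit on its surface and holds haematopoietic stem and progenitor cells. The 4 Fli-1 knockout (KO) libraries and 4 wild-type (WT) libraries came from cells sorted again after 6 days on E4orf1 vascular niche cells, a feeder layer of endothelial cells, in serum-free medium with SCF, Flt3 ligand and thrombopoietin. Deletion of Fli-1, an ETS family transcription factor of blood and endothelial cells, was induced with 4-hydroxytamoxifen. Reads assigned to genes numbered 22329492 to 25212300 per KO library and 18870601 to 21858278 per WT library. A KO library held 16140 ± 102 genes with at least 1 read (mean ± SD, n = 4) and a WT library 15420 ± 54.4 (n = 4). The labels do not say that the libraries came from separate animals or cultures, so the p-values measure the spread between these libraries, which may be technical. The design holds a single comparison, KO against WT, and log2 fold changes below are KO relative to WT.

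Fli1 itself was lower in every KO library than in any WT library. The gene lies on chromosome 9 from 32422204 to 32542861 on the minus strand (GRCm38), where GENCODE annotates it as protein-coding with no exon shared with another gene. Its level was 24.2 ± 1.05 CPM (SD, n = 4; CPM is the counts-per-million scale) in KO and 57.3 ± 3.75 CPM (SD, n = 4) in WT, so that KO libraries kept 42.1% of the WT level. The log2 fold change was -1.25 with a standard error (SE) of 0.057, and the adjusted p was 9.0e-08 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. A two-sided exact permutation test on the 8 log2 CPM values gave p = 0.0286, the smallest that 4 against 4 libraries allow. The test ignores the pairing by replicate number, and relabelling within pairs could not reach so small a p. The deleted exons are not given in the labels, and the counts are for the whole gene, so reads from exons that remain would still be counted. Cells in which the deletion did not occur would add reads too. The level that remains therefore cannot tell how complete the deletion was.

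The other members of the heptad, the transcription factors that bind together at stem cell enhancers, moved little. Of the 7 heptad genes, Tal1 and Lmo2 rose, Fli1 fell and 4 did not pass the test. Adjusted over the list alone, 1 gene rose and 1 fell. Tal1 was at 81.0 ± 6.52 CPM in KO and 60.9 ± 6.91 CPM in WT (log2 fold change 0.41, SE 0.084), and Lmo2 at 562 ± 20.2 and 483 ± 61.9 CPM (0.22, SE 0.085; SD, n = 4 each). Values for the closest ETS relative, Erg, were 139 ± 5.52 CPM in KO and 145 ± 14.3 CPM in WT, with a log2 fold change of -0.07 (SE 0.066). Gata2 had a log2 fold change of 0.25 (SE 0.209), Runx1 of -0.14 (SE 0.081) and Lyl1 of -0.03 (SE 0.049). With the replicate number as a block, Gata2 passed the edgeR threshold upward (adjusted p = 0.0109) and Runx1 downward (adjusted p = 0.0241), making 3 heptad genes higher and 2 lower. The call for Lmo2 was lost in the edgeR test without KO replicate 1, 2, 3 or 4 or WT replicate 2, with adjusted p between 0.0597 and 0.104, and without a low-count filter (adjusted p = 0.0694), which leaves 1 heptad gene higher, while Erg passed without WT replicate 1 (-0.14, adjusted p = 0.00536). As a set, the heptad did not pass camera, a test that ranks a list against all other genes (adjusted p = 0.632).

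**Figure D1:**
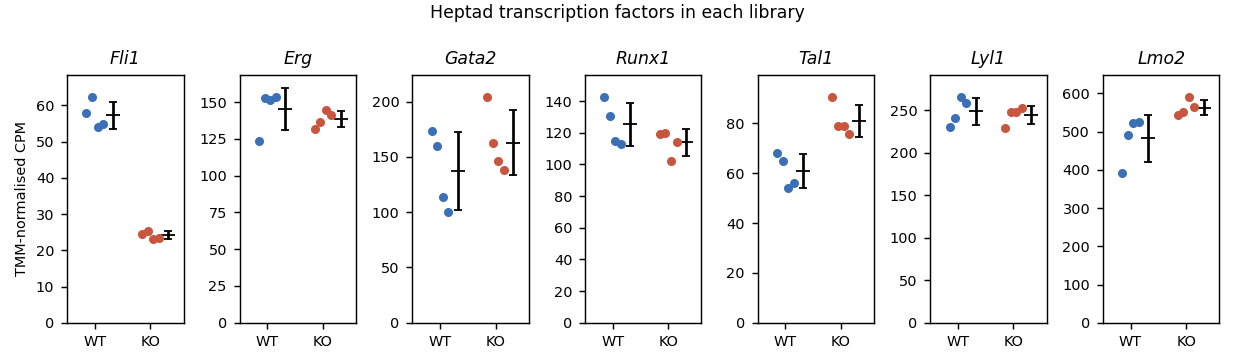
TMM-normalised CPM (y axis, linear, from 0) of the 7 heptad transcription factors in each of the 4 WT (blue) and 4 KO (red) libraries, replicates 1 to 4 from left to right within a group. Bars are the mean and SD of 4 libraries; Fli1 is at 24.2 CPM in KO and 57.3 CPM in WT, Tal1 and Lmo2 lie higher in KO, and the other 4 did not pass the edgeR test.

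Other ETS factors were more often higher than lower in KO. Of 16 tested, 11 rose, 2 fell and 3 did not pass, and the counts adjusted over the list alone were 11 and 2. Spib, which acts in B cells and plasmacytoid dendritic cells, was at 22.4 ± 3.81 CPM in KO and 2.81 ± 0.240 CPM in WT (log2 fold change 2.99, SE 0.136). Macrophage and dendritic cell genes (median 2.86) and mast cell genes (median 1.29) rose in the same KO libraries. Etv4 rose by 1.34 (SE 0.142) and Etv5 by 0.62 (SE 0.089) on the log2 scale, whereas Elk4 was lower (-0.73, SE 0.062). Spi1, which encodes PU.1, had a log2 fold change of 0.04 (SE 0.049) at 191 ± 10.6 CPM in KO and 186 ± 9.87 CPM in WT. The list passed camera upward (adjusted p = 0.0185), but not with an estimated inter-gene correlation (adjusted p = 0.614). The small change of Elf1 (-0.12) was no longer called without KO replicate 1 or 4 or WT replicate 3 or 4 (edgeR adjusted p between 0.0505 and 0.0629), which left 1 lower gene, and that of Etv6 (0.11) without KO replicate 2, 3 or 4 or WT replicate 3 or 4 (adjusted p between 0.0540 and 0.0975). Ets1 (0.29, edgeR adjusted p = 0.0697) passed without KO replicate 3 or 4 or WT replicate 2 (adjusted p between 0.0345 and 0.0494), and with library size only Elf1 did not pass (adjusted p = 0.152) while Ets1 did (adjusted p = 0.0431).

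Most of the measured genes differed between the genotypes. Of 13020 genes tested, 8771 (67.4%) changed, 4379 upward and 4392 downward. TMM scaling assumes that most genes do not change and sets the median log2 fold change near 0 (-0.0046 here). The near-equal split, and the direction of small changes, therefore depend on the scaling. With library size only, 4857 genes were higher and 3961 lower. A difference of at least 2-fold was reached by 956 of the higher and 806 of the lower genes, and one of at least 8-fold by 228 and 39. For 8140 genes (62.5%) the CPM ranges of the 4 KO and the 4 WT libraries did not overlap, against 2.86% by chance. The first principal component held 77.7% of the variance and separated the genotypes.

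The largest rises were taken among changed genes with a mean of at least 5 CPM and no overlap between groups, unnamed gene models aside. They included genes of mast cell granules and of dendritic cells. Mcpt1, a mucosal mast cell chymase, was at 259 ± 49.0 CPM in KO and 0.496 ± 0.386 CPM in WT (SD, n = 4 each; log2 fold change 9.01, SE 0.299). The neighbouring protease genes Mcpt2 (158 ± 47.2 against 0.750 ± 0.355 CPM) and Mcpt4 (142 ± 39.3 against 0.688 ± 0.216 CPM) lie with Mcpt1 on chromosome 14, between 56017971 and 56062313. The mast cell tryptase Tpsb2 stood at 152 ± 38.4 CPM in KO and 3.33 ± 0.858 CPM in WT. Xcr1 (26.6 ± 11.9 against 0.506 ± 0.177 CPM), Clec9a (17.5 ± 6.46 against 0.360 ± 0.269 CPM), Cadm1 (24.5 ± 6.34 against 0.446 ± 0.221 CPM) and the endosomal RNA sensor Tlr3 (12.4 ± 5.82 against 0.364 ± 0.296 CPM) are all expressed by the cross-presenting class of dendritic cells. Dnase1l3, which encodes a secreted DNase, and Plbd1, which encodes a phospholipase B-like protein, complete the 10 highest under these limits, with log2 fold changes of 7.05 (SE 0.612) and 5.14 (SE 0.459). WT counts behind Dnase1l3 came to 8 reads over the 4 libraries, which leaves the size of its change loosely fixed. Without 1 library, the fold moved by over 1.5 times for Mcpt1 (9.71 without WT replicate 2), Clec9a (6.25 without WT replicate 1) and Dnase1l3 (7.94 without WT replicate 4), each in the same direction.

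Under the same limits the largest falls included secreted and granule proteins of myeloid cells. F13a1, the coagulation factor XIII A chain, was at 36.5 ± 29.1 CPM in KO and 987 ± 390.0 CPM in WT (log2 fold change -4.76, SE 0.703). Slpi, a secreted protease inhibitor, was at 8.06 ± 1.48 and 120 ± 40.8 CPM, and Lcn2, the iron-siderophore carrier of neutrophil granules, at 0.534 ± 0.432 and 23.6 ± 25.6 CPM. Tgfb3, a TGF-beta ligand, was at 0.461 ± 0.156 CPM in KO and 22.0 ± 8.10 CPM in WT (-5.55, SE 0.352). Gzmc, a granzyme, was at 1.08 ± 0.776 and 34.0 ± 14.9 CPM. Aldh1l2 and Trib3 were among the 10 lowest (Aldh1l2, a mitochondrial folate enzyme, 1.58 ± 0.287 against 26.5 ± 3.51 CPM; Trib3, a pseudokinase, 4.37 ± 0.420 against 58.2 ± 19.6 CPM), as were the secretory cell transcription factor Bhlha15 (-3.96, SE 0.342) and the copper carrier Cp (-3.60, SE 0.493). Elane, neutrophil elastase, had the largest standard error of the 20 genes, at 9.23 ± 8.71 CPM in KO and 132 ± 176 CPM in WT (-3.84, SE 1.23, edgeR adjusted p = 0.0310). WT replicate 1 held 393 CPM of Elane and the other WT libraries 25.7 to 79.6 CPM, and without it the log2 fold change was -2.29 (adjusted p = 0.0506). Without KO replicate 1 it was -4.74, and without KO replicate 2, 3 or 4 the call was lost too (adjusted p between 0.0764 and 0.0804). Without WT replicate 1 the change of Lcn2 was -4.34, and without KO replicate 1 those of Lcn2, F13a1 and Gzmc were -6.10, -5.40 and -5.59.

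**Figure D2:**
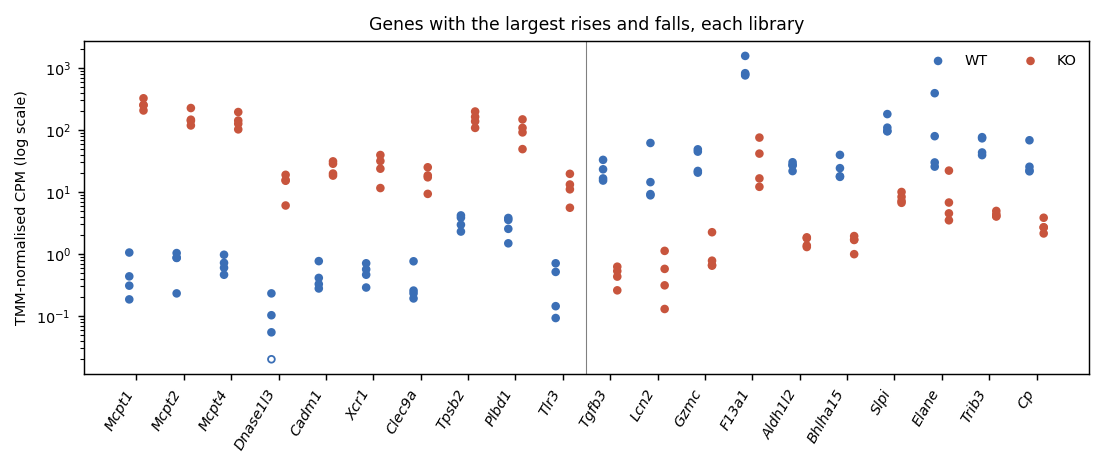
TMM-normalised CPM (y axis, log scale) in each of the 4 WT (blue) and 4 KO (red) libraries for the 10 genes with the largest rises (left of the line) and the 10 with the largest falls (right) under the rule for named genes; an open circle marks a library with no read, drawn at the foot of the axis. The groups do not overlap for any of the 20, Mcpt1 has the largest rise (259 against 0.496 CPM), and Elane has the widest spread relative to its mean among the WT libraries.

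Among the lists of lineage genes, those of mast and antigen-presenting cells rose and that of granulocytes and monocytes fell. In the mast cell, basophil and eosinophil list, 7 of 14 tested genes rose, 1 fell and 6 did not pass, with the same 7 and 1 when adjusted over the list alone. Beside Mcpt4 and Tpsb2, the chymase Cma1 was at 34.5 ± 13.2 CPM in KO and 3.15 ± 1.15 CPM in WT, and Cpa3, mast cell carboxypeptidase, at 81.8 ± 24.8 and 26.8 ± 7.95 CPM (log2 fold change 1.61, SE 0.275). Ccl9, a chemokine, was the member that fell (-0.69, SE 0.181); its edgeR call was lost with the replicate block (adjusted p = 0.0697). The median log2 fold change was 1.29, and the list passed camera (adjusted p = 2.6e-04), though not with an estimated correlation (adjusted p = 0.614). Without WT replicate 1, 11 of 16 tested members rose, without a low-count filter 11 of 20 and with the replicate block 10 of 14. In the macrophage and dendritic cell list, 12 of 14 rose, 1 fell and 1 did not pass, and the list alone gave 12 and 1. The MHC class II invariant chain Cd74 reached 650.2 ± 237 CPM in KO against 57.4 ± 14.3 CPM in WT, and the class II transactivator Ciita 32.8 ± 8.996 against 2.56 ± 0.408 CPM. Itgax, which encodes CD11c, and Siglech, of plasmacytoid dendritic cells, had log2 fold changes of 2.78 (SE 0.138) and 4.97 (SE 0.326). The lysosomal macrophage marker Cd68 was the member that fell (-0.51, SE 0.105). The median of this list was 2.86 (camera adjusted p = 1.9e-07; adjusted p = 0.396 with an estimated correlation).

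The granulocyte-monocyte list had 9 of 17 tested genes lower, 1 higher and 7 that did not pass, and adjusting over the list alone gave the same counts. Csf3r, the G-CSF receptor, was at 109 ± 10.2 CPM in KO and 303 ± 4.87 CPM in WT (log2 fold change -1.47, SE 0.058). The M-CSF receptor gene Csf1r (-1.53, SE 0.219), the integrin gene Itgam (-1.54, SE 0.112) and the granulocyte transcription factor Gfi1 (-1.29, SE 0.134) were lower as well. Lyz2, lysozyme, was the member that rose (51.1 ± 11.8 against 21.7 ± 10.4 CPM). The median was -1.09 and camera gave an adjusted p of 0.00535, against an adjusted p of 0.718 with an estimated correlation. The call was also lost when genes held by more than 1 list were removed (adjusted p = 0.179). WT replicate 1 had 182 CPM of Csf1r against 106 to 115 CPM in the other WT libraries, and without it 8 members were lower and 2 higher.

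Genes of platelets and of lymphoid and erythroid cells did not move as sets. In the megakaryocyte and platelet list, 7 of 21 tested genes fell, 2 rose and 12 did not pass, with the same 7 and 2 over the list alone. Platelet integrin Itgb3 was at 33.2 ± 3.41 CPM in KO and 146 ± 35.01 CPM in WT (log2 fold change -2.14, SE 0.176), and the chemokine gene Ppbp fell by 2.70 (SE 0.309) on the log2 scale. Plek fell by 0.69 (SE 0.060), while Gp9 rose by 1.07 (SE 0.141). With the replicate block 5 members were higher and 9 lower, with DESeq2 11 of 23 were lower, and without WT replicate 1 there were 4 higher. Leaving out KO replicate 1, 3 or 4 or WT replicate 2, 3 or 4, or the low-count filter, left 1 higher. Camera gave an adjusted p of 0.197 for this list, which passed downward without KO replicate 1 (adjusted p = 0.0489) or WT replicate 4 (adjusted p = 0.0475). Of 16 erythroid genes 6 rose, 1 fell and 9 did not pass, again 6 and 1 over the list alone (camera adjusted p = 0.229). Hemgn was at 27.3 ± 2.38 CPM in KO and 10.4 ± 2.26 CPM in WT, and Blvrb, biliverdin reductase B, fell by 1.98 (SE 0.145). The erythroid count was 10 higher with the replicate block, and 2 members fell without KO replicate 1 or WT replicate 3 or 4. Of 15 lymphoid genes 5 rose, 7 fell and 3 did not pass, the same over the list alone (camera adjusted p = 0.845), with a median of -0.15 and a mean of 0.11. Dntt, which adds nucleotides at antigen receptor joints in early lymphoid cells, was at 139 ± 55.8 CPM in KO and 1037 ± 344 CPM in WT, and Cd79b fell by 1.13 (SE 0.079). Ccr9, a homing receptor of thymus-seeding and plasmacytoid dendritic cells, rose by 2.70 (SE 0.262) and the lymphoid transcription factor Ikzf1 by 0.58 (SE 0.084).

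Stem cell genes moved in both directions. In the stem cell identity list, 12 of 29 tested genes rose, 8 fell and 9 did not pass, the same over the list alone, with a median of 0.04 (camera adjusted p = 0.874). The mean was -0.08, opposite in sign to the median. Ly6a, which encodes the Sca-1 antigen of the sorting gate, was at 94.6 ± 2.93 CPM in KO and 212 ± 7.01 CPM in WT (log2 fold change -1.16, SE 0.036). Kit, the other gene of the gate, was at 331 ± 22.1 and 256 ± 18.4 CPM (0.37, SE 0.060). The transcription factor genes Mecom and Meis1 rose by 1.03 (SE 0.112) and 0.52 (SE 0.058), and Procr, the stem cell surface receptor EPCR, by 1.36 (SE 0.200) from a low level of 2.29 ± 0.463 CPM in WT. Cd34 had 836 ± 39.0 CPM in KO and 864 ± 115 CPM in WT, which did not pass the edgeR test, though it did without WT replicate 1 (-0.14, adjusted p = 0.0158).

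Replication and ribosome biogenesis genes rose together. Of 25 genes of the G1/S transition and replication, 23 rose, 1 fell and 1 did not pass, and the list alone gave 23 and 1. The helicase subunit gene Mcm5 was at 479 ± 14.1 CPM in KO and 270 ± 17.9 CPM in WT (log2 fold change 0.82, SE 0.048), with Mcm3, Mcm4 and Mcm7 between 0.58 and 0.63. The D-type cyclin gene Ccnd3 was the member that fell (-0.20, SE 0.053). The median was 0.46, and camera gave an adjusted p of 8.5e-09, against an adjusted p of 0.396 with an estimated correlation. In the MYC and ribosome biogenesis list, 23 of 24 genes rose, also over the list alone, with a median of 0.45 (camera adjusted p = 4.7e-09; adjusted p = 0.396 with an estimated correlation). The processome gene Utp20 rose by 0.85 (SE 0.042), Bop1 by 0.75 (SE 0.038) and the pyrimidine synthesis gene Cad by 0.63 (SE 0.033). The remaining member was Myc itself, at 373 ± 45.3 CPM in KO and 797 ± 47.7 CPM in WT (-1.10, SE 0.083). Of 25 mitotic genes in the G2/M list, 10 rose, 2 fell and 13 did not pass, with 9 and 2 over the list alone (camera adjusted p = 0.229). Birc5 rose by 0.56 (SE 0.063) and Kif20a by 0.45 (SE 0.052). In the list of quiescence genes and cyclin-dependent kinase inhibitors, 7 of 22 rose, 9 fell and 6 did not pass, the same over the list alone (camera adjusted p = 0.564). Txnip, a glucose-responsive inhibitor of thioredoxin, was at 265 ± 21.6 CPM in KO and 760 ± 48.0 CPM in WT, the inhibitor gene Cdkn1b (p27) fell by 0.59 (SE 0.059), and Klf4 rose by 3.05 (SE 0.263). The median of this list was -0.13 and its mean 0.22. Mast cell (median 1.29) and macrophage and dendritic cell (median 2.86) genes rose in the same KO libraries as the replication and ribosome biogenesis genes.

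Glycolysis genes fell and cholesterol synthesis genes rose. Of 20 glycolysis genes, 17 fell, 1 rose and 2 did not pass, and 18 fell when adjusted over the list alone. The glucose transporter gene Slc2a3 was at 101 ± 2.61 CPM in KO and 217 ± 9.04 CPM in WT (log2 fold change -1.10, SE 0.037), Aldoc at 19.7 ± 1.14 and 56.6 ± 3.24 CPM, the pyruvate dehydrogenase kinase gene Pdk1 at 176 ± 7.98 and 422 ± 33.9 CPM, and Gpi1 at 1004 ± 68.8 and 2146 ± 113 CPM. Ldhb, the lactate dehydrogenase B subunit, was the member that rose (2.64, SE 0.181). The median was -0.64 (camera adjusted p = 4.7e-09; adjusted p = 0.396 with an estimated correlation). In the same KO libraries mast cell genes (median 1.29) and macrophage and dendritic cell genes (median 2.86) rose and granulocyte-monocyte genes (median -1.09) fell. Of 21 cholesterol synthesis genes, 14 rose, 1 fell and 6 did not pass, the same over the list alone, with a median of 0.42 (camera adjusted p = 3.0e-04; adjusted p = 0.614 with an estimated correlation). Dhcr24, which reduces desmosterol to cholesterol, was at 204 ± 3.87 CPM in KO and 74.8 ± 5.30 CPM in WT, and the regulator gene Srebf2 rose by 0.54 (SE 0.052). Pcsk9, a degrader of the LDL receptor, was the member that fell (-0.97, SE 0.276).

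Signalling lists held strong single changes without passing the main camera test as sets. Fry, which does not compare a list with other genes, called the cytokine (adjusted p = 0.0023), Notch (adjusted p = 9.4e-04) and p53 (adjusted p = 0.0023) lists lower. It called no other list of this paragraph. Of 31 cytokine receptor and JAK-STAT genes, 16 fell, 7 rose and 8 did not pass, the same over the list alone (camera adjusted p = 0.0635). Stat5b fell by 0.55 (SE 0.031) and Pim1, a STAT5 target kinase, by 0.96 (SE 0.058), while Gas6, a TAM receptor ligand, rose by 1.79 (SE 0.170). This list passed camera without KO replicate 1 or 4 or WT replicate 3 or 4, with adjusted p between 0.0259 and 0.0461, and without a low-count filter (adjusted p = 0.0144). Of 18 Notch pathway genes 6 fell, 2 rose and 10 did not pass (camera adjusted p = 0.148), with Notch2 up by 0.71 (SE 0.040), and the ligand gene Jag2 (-1.04, SE 0.074) and Dtx4 (-1.30, SE 0.099) lower. Of 28 interferon response genes 12 rose, 6 fell and 10 did not pass (camera adjusted p = 0.229, and 0.0227 without WT replicate 1). Ifit2 rose by 1.43 (SE 0.077) and Isg20 fell by 1.15 (SE 0.100). Of 22 NF-kB and inflammatory genes 8 rose, 5 fell and 9 did not pass (camera adjusted p = 0.729), among them Icam1 (0.65, SE 0.064) and Ier3 (-1.43, SE 0.131). Of 22 p53 targets 10 fell, 6 rose and 6 did not pass (camera adjusted p = 0.138, and 0.0433 without a low-count filter), and the mTORC1 inhibitor gene Ddit4 was at 40.1 ± 2.48 CPM in KO and 99.98 ± 8.34 CPM in WT. Of 16 BCL2 family genes 8 rose, 5 fell and 3 did not pass (camera adjusted p = 0.874), with the pro-apoptotic gene Bmf down by 1.63 (SE 0.103) and the anti-apoptotic gene Bcl2l1 up by 0.98 (SE 0.068). Of 28 adhesion and homing genes 10 rose, 10 fell and 8 did not pass (camera adjusted p = 0.774). Tln1, talin, was at 1104 ± 26.0 CPM in KO and 776 ± 12.8 CPM in WT, and Selplg, the P-selectin ligand, at 326 ± 17.7 and 567 ± 46.9 CPM. In these 7 lists the counts adjusted over the list alone were the same as those over all genes.

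Endothelial and stromal markers were examined as genes of the feeder layer and of other niche cells. Of 16 endothelial genes 6 rose, 4 fell and 6 did not pass, the same over the list alone (camera adjusted p = 0.632). Cdh5, VE-cadherin, was at 4.18 ± 1.57 CPM in KO and 0.11 ± 0.087 CPM in WT, where 9 reads were counted over the 4 libraries. Kdr was at 2.26 ± 0.657 CPM in KO and 0.139 ± 0.115 CPM in WT. Pecam1, which blood progenitors express too, fell by 0.57 (SE 0.052) to 111 ± 6.78 CPM, and the apelin gene Apln by 2.27 (SE 0.193). Of 13 stromal and matrix genes 8 rose, 1 fell and 4 did not pass, the same over the list alone (camera adjusted p = 0.155), with Fn1, fibronectin, at 13.7 ± 1.19 CPM in KO and 4.18 ± 1.11 CPM in WT and Fbn1, fibrillin, at 2.27 ± 0.681 and 0.173 ± 0.043 CPM. Col1a2 was at 3.28 ± 1.32 CPM in KO and 0.240 ± 0.224 CPM in WT. Under a stricter low-count filter 6 stromal genes were tested and 2 rose, and without KO replicate 3 or 4 the number that fell was 2. Whether feeder cells passed the sort into the KO libraries was not tested, and these values cannot tell. Mitochondrially encoded genes, the remaining list, had no gene row in the count table and were not tested.

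**Figure D3:**
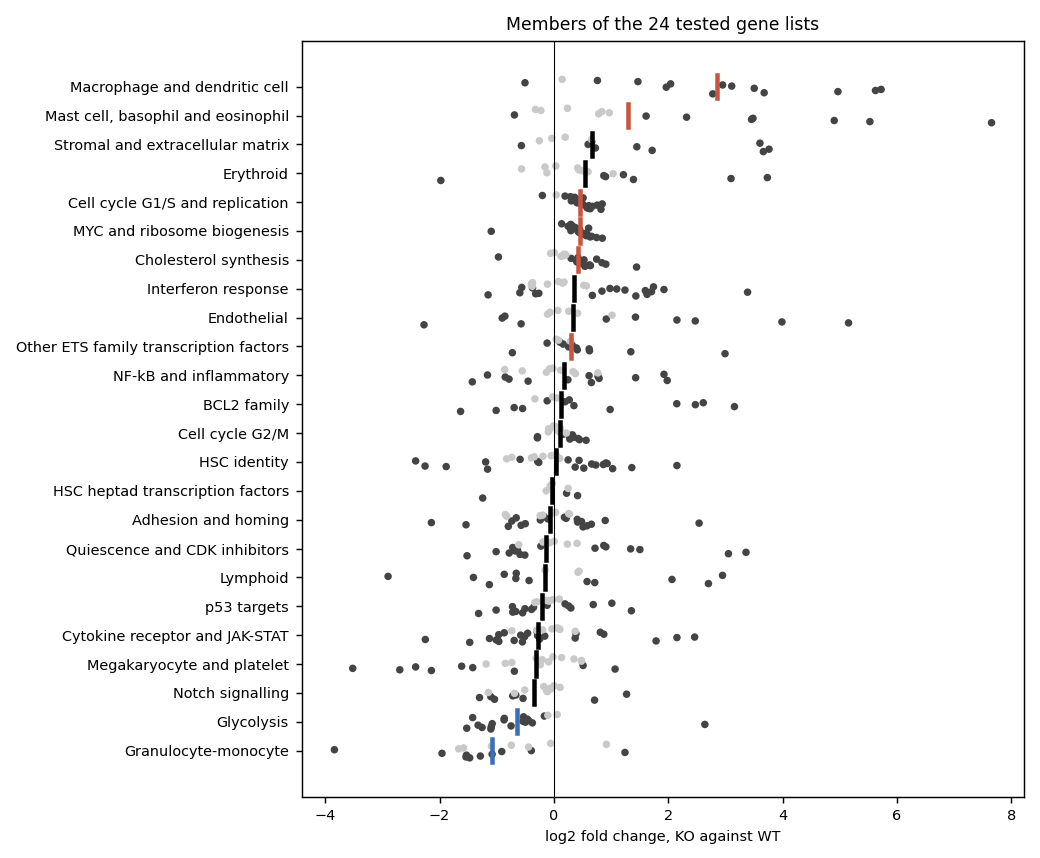
Log2 fold changes of the tested members of 24 gene lists (x axis, KO relative to WT; lists on the y axis, ordered by median; points are spread vertically for legibility). Dark points passed the edgeR test and grey points did not; the vertical bar is the list's median, red or blue where camera with a preset correlation called the list higher (6 lists) or lower (2 lists) in KO and black otherwise, and with an estimated correlation none of the 24 was called (1 had an unadjusted p under 0.05).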

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

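In 18 of 318 sets of 4 values (a gene or library measure in KO or in WT), 1 library stood apart from the other 3 by the ratio of its gap to the group's whole range, above Dixon's critical value. Chance alone would give about 15.9, a figure that is only approximate because some of the genes were added to the examined set after their values had been seen. Of the 18, however, 11 fell on WT replicate 1. The tests of paralogs, of dilution and of admixture described here were chosen only after the results were seen.

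WT replicate 1 had more of several myeloid transcripts than the other WT libraries. Elane was at 393 CPM against 25.7 to 79.6 CPM (ratio 0.853), Lcn2 at 61.8 against 8.84 to 14.4 CPM (0.894), F13a1 at 1570 against 761 to 826 CPM (0.919), Slpi at 181 against 95.2 to 109 CPM (0.836), Cp at 68.4 against 21.6 to 25.6 CPM (0.915), Csf1r at 182 against 106 to 115 CPM (0.886), Ctsg at 685 against 346 to 368 CPM (0.932) and Cd68 at 79.5 against 57.7 to 61.3 CPM (0.835). It also had 0.762 CPM of Clec9a against 0.192 to 0.257 CPM (0.886). It had less Dntt, 527 against 1160 to 1280 CPM (0.846), and less Erg, 124 against 151 to 153 CPM (0.922). Without this library 8872 genes changed instead of 8771.

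Other libraries stood apart in single genes. In KO replicate 1, Gzmc was at 2.24 CPM against 0.648 to 0.780 CPM (ratio 0.917), Blvrb at 9.54 against 6.47 to 6.98 CPM (0.832) and Slc18a2 at 59.7 against 39.6 to 40.5 CPM (0.953). Cd79b was at 25 CPM in KO replicate 2 against 19.2 to 20 CPM (0.865). In WT replicate 2, Gpi1 was at 1980 CPM against 2180 to 2220 CPM (0.866), Egln3 at 618 against 708 to 713 CPM (0.946) and Bnip3 at 187 against 240 to 247 CPM (0.884).

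The count of changed genes was compared with other splits of the libraries. Of the 35 splits of the 8 libraries into 4 and 4, only the real one (1 split) gave 8771 genes or more in edgeR. The highest of the others gave 6. Every other split puts KO and WT libraries together in both groups, so the genotype difference widens the spread within groups and keeps calls few. The comparison therefore cannot tell how many calls chance alone would give. Since the replicate numbers pair the libraries by the rule used here, the closest comparison is with the 7 other splits that part all 4 pairs. Those gave 0 genes each in edgeR, with 9 to 424 genes at an unadjusted p under 0.05, but 8 splits are too few for a share under 0.05. The split with 6 genes set replicates 1 and 2 against 3 and 4 and kept every pair whole, and the 24 splits that part 2 pairs gave 0 genes, with 6 to 1020 at an unadjusted p under 0.05.

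The rise of mast cell and dendritic cell genes was weighed first. Cpa3, a carboxypeptidase outside the families of near-identical protease genes, rose by 1.61 on the log2 scale (SE 0.275), so the rise was not confined to those families. Its rise cannot tell whether reads were shared or lost among the near-identical genes, and the sizes of their changes stay uncertain. Carry-over of mature cells through the sort predicts that other abundant markers rise too, and 75% of 20 further mast cell markers and 68% of 25 further dendritic cell markers did, though 9 of the former 20 and 15 of the latter 25 are at 5 CPM or more in WT cells. Of the mast cell markers 1 fell, or 4 with the replicate block and 2 without KO replicate 1, and the count of rises was 15 with the block too. Of the dendritic cell markers 5 fell, with or without the block. Carry-over therefore stays open, with markers such as Cd74 (650.2 CPM), Mcpt1 (259 CPM) and Cpa3 (81.8 CPM) present in KO. A lineage-negative gate with c-Kit and Sca-1 should, however, remove dendritic cells and, since mast cells carry c-Kit, may not remove mast cells. A change of the knockout progenitors themselves toward these lineages predicts the same values and stays open, untested.

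The fall of glycolysis genes was weighed next. The choice among the scalings used is argued against, as the median log2 fold change of the list was -0.601 or lower with both other scalings. These scalings differ little, the TMM factors lying between 0.974 and 1.018, and a difference in total RNA per cell was not tested. A lower share of progenitors, with the other cell types kept in proportion, would raise the markers of those types alike. Instead the medians of the mast cell list and of the macrophage and dendritic cell list lay above that of the granulocyte-monocyte list. The differences were 2.38 (bootstrap SE 0.959) and 3.96 (bootstrap SE 0.629), with errors that treat genes as independent. This argues against such an even dilution as the whole cause. An uneven dilution, with more mast and dendritic cells and fewer granulocytes and monocytes, predicts the same medians and stays open. An admixture of mature mast or dendritic cells alone would lower the transcripts of dividing progenitors by about as much as the glycolysis genes. Instead 23 of 25 replication genes (median 0.455, SD of members 0.234) and 23 of 24 ribosome biogenesis genes (median 0.448, SD 0.36) rose, with medians above that of the glycolysis genes by 1.09 or more (bootstrap SE 0.192 and 0.193), and Erg changed by -0.07 (SE 0.066). These errors also treat genes as independent and are too small. The estimated inter-gene correlation was 0.341 in the replication list, 0.33 in the ribosome biogenesis list and 0.368 in the glycolysis list. By their direction, the replication and ribosome biogenesis genes argue against an admixture of mature, non-dividing cells as the whole cause. The heptad median lay above the glycolysis median by 0.618 (bootstrap SE 0.271, SD of members 0.549). For the stem cell identity list the difference was 0.68 (bootstrap SE 0.289), less than the SD of its members (1.05), with 7 of 29 at or below the glycolysis median. That list does not decide, and an admixture of dividing precursors was not tested. A contribution of admixture stays open, as Ly6a fell by 1.16 and stem cell genes moved both ways. A candidate explanation is a weaker hypoxia response in KO cells, since 84% of 25 hypoxia genes outside glycolysis fell. Whether oxygen, cell density or medium differed between the cultures of the genotypes was not recorded in the labels, and the knockout itself stays open as the biological explanation.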

How the results depend on the processing

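The alternatives without Rn45s, with the estimated correlation joined to the block, and all those for the 4 later lists were chosen after seeing the data. The count of changed genes stayed between 7889 (stricter filter) and 9171 (no filter) across settings and between 8249 and 8872 with 1 library left out; with the replicate block it was 9084 (4530 higher, 4554 lower), of which 8665 were among the 8771. With library size only, 4857 genes were higher and 3961 lower. The log2 fold change of Fli1 lay between -1.28 and -1.20 throughout. The number of lists called lower was 2 in the main camera test, 4 without a low-count filter, 6 with fry, 1 without shared genes and between 2 and 4 with 1 library left out (4 without KO replicate 1 or WT replicate 4), and the number higher was 6 or 7 with 1 library left out. With an estimated correlation camera called 0 higher and 0 lower, with or without the replicate block. In that test 1 list without and 2 with the block had an unadjusted p under 0.05, and fry called 14. Those that fry called and the main camera test did not were the heptad, cytokine, Notch and p53 lists (lower) and the endothelial and stromal lists (higher). The cause of these differences was not tested, except that fry does not compare a list with other genes. The heptad list includes the deleted gene, Fli1. Without Fli1 and the genes shared with other lists, the heptad list pointed upward in camera and was not called (adjusted p = 0.689). Fry was not run without Fli1, so its call does not show that the other heptad genes fell. For single named genes, 2387 values stayed on the same side of the threshold, 27 lost a call, 12 gained one and none changed direction with a call. The 2387 include changes of sign in genes without a call. Across settings Lyl1 ranged from -0.061 to 0.017 and Gzmb from -0.0094 to 0.614. The block changed the calls of Runx1, Gata2, Ccl9 and Mcpt8 and of no other of the 153 genes examined by name, and no camera call of the 24 fixed or 4 later lists. The later list of mast cell markers lost its camera call with the stricter filter (adjusted p = 0.147), where 8 of 13 tested members rose; the other 3 later lists kept theirs in every camera setting run with the preset correlation. Besides the genes already named with a lost or gained call, Elk3 passed with library size only (adjusted p = 0.0139), Ets1 with DESeq2 (adjusted p = 0.0445), Gata2 with limma-voom (adjusted p = 0.0469), and Atf3 and Wars lost theirs without certain single libraries. Other counts of list members that a tool moved by over 1.5 times were the higher granulocyte-monocyte genes, 2 instead of 1 with limma-voom, the lower stromal genes, 2 instead of 1 with DESeq2, and the lower mast cell markers of the later list, 2 instead of 1 with either tool. Low depth limits genes with few WT reads.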

Other observations

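The 4 lists described here were written after the genes with the largest changes had been seen and before the values of their own members were.

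Among 11 tested genes of the chymase and granzyme cluster on chromosome 14 (55941451 to 56262260, GRCm38), 7 rose and 2 fell. The mast cell chymase genes at its start rose, from Cma1 (34.5 CPM in KO and 3.15 CPM in WT) to Mcpt4 (142 and 0.688 CPM). Beyond them, Mcpt8, a basophil protease gene, had 18.9 and 23.7 CPM and did not pass, though with the replicate block it passed downward (adjusted p = 0.0054). Ctsg, the neutrophil protease cathepsin G, fell from 438 CPM in WT to 113 CPM in KO (log2 fold change -1.96, SE 0.357), and Gzmc fell from 34.0 to 1.08 CPM, while Gzmb had 9.29 CPM in KO and 7.91 CPM in WT and did not pass.

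Genes of the hypoxia response outside glycolysis fell: 21 of 25 tested were lower and 4 did not pass, with 22 lower when adjusted over the list alone and a median log2 fold change of -0.80. Vegfa, the vascular growth factor, was at 58.8 ± 3.61 CPM in KO and 223 ± 5.81 CPM in WT (SD, n = 4 each; -1.92, SE 0.045). The prolyl hydroxylase gene Egln3 (194 ± 15.4 against 688 ± 46.9 CPM), Ndrg1 (34.9 ± 4.96 against 162 ± 16.9 CPM) and the mitophagy receptor gene Bnip3 (54.2 ± 8.63 against 229 ± 27.9 CPM) were lower too. Camera over the 4 later lists gave an adjusted p of 1.6e-17, and adjusted p = 0.0547 with an estimated correlation. Of the further mast cell markers 15 of 20 rose, 1 fell and 4 did not pass, while with the replicate block 15 rose and 4 fell and without KO replicate 1 the number that fell was 2 (camera adjusted p = 0.0051; adjusted p = 0.331 with an estimated correlation). The serotonin synthesis gene Tph1 was at 12.7 ± 1.96 CPM in KO and 1.24 ± 0.582 CPM in WT, and Slc18a2, the vesicular monoamine transporter, was the member that fell without the block (-0.93, SE 0.227). Of the further dendritic cell markers 17 of 25 rose, 5 fell and 3 did not pass (camera adjusted p = 0.0021; adjusted p = 0.206 with an estimated correlation), with Cst3, cystatin C, at 518 ± 147 and 208 ± 24.4 CPM.

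The fall of amino acid stress genes was examined because Trib3 and Aldh1l2, targets of the transcription factor ATF4, were among the largest falls. A weaker ATF4 response in KO cells predicts that most other ATF4 and amino acid genes fall, and 80.6% did: 25 of 31 were lower, 2 were higher and 4 did not pass (camera adjusted p = 6.6e-08; adjusted p = 0.206 with an estimated correlation). The asparagine synthetase gene Asns was at 70.0 ± 5.38 CPM in KO and 187 ± 20.9 CPM in WT, Atf5 at 20.6 ± 0.919 and 90.8 ± 10.8 CPM, and Gpt2 at 12.9 ± 1.34 and 58.4 ± 1.76 CPM, whereas Atf3 rose by 1.58 (SE 0.486) and Wars by 0.13 (SE 0.047). The Atf3 call was lost without KO replicate 4 or WT replicate 3 (adjusted p = 0.0508 and 0.0568), and that of Wars without KO replicate 3 or 4 or WT replicate 2 or 4 (adjusted p between 0.0545 and 0.0841). In the same KO libraries mast cell genes (median 1.29) and macrophage and dendritic cell genes (median 2.86) rose and granulocyte-monocyte genes (median -1.09) fell, so a change in the mix of cells may also contribute. The values are consistent with the hypothesis, and a difference in medium between the cultures, which predicts the same, was not tested.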
